A study of Danio rerio with 12 samples.

How the data were processed

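Ovary RNA of 12 adult female zebrafish of the AB strain, 5 months old, was measured on 12 Agilent 2-colour arrays. Per the labels, 6 fish had been held for 96 h in control water and 6 in water with a nominal 50 µg/L of haloperidol, a blocker of dopamine D2 receptors. Whole ovaries went into RNAlater and RNA was extracted with TRI Reagent, with RNA integrity numbers from 5.7 to 9.3. Each array carried amplified ovary RNA of 1 fish labelled with Cy5 and a common reference pool labelled with Cy3. Per the labels, that pool came from gonads and brains of both sexes and livers of females. No dye was swapped (0 swaps), so a ratio above 0 on the log2 scale means more signal in ovary than in the pool, and the same dye and pool stand on both sides of the contrast of treatments.

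Per the series text, each treatment had 2 tanks with 6 females each, 3 fish per tank went onto arrays, and samples with the better RNA were generally preferred. The labels do not give the tank of a fish, so the fish was the unit, and p values measure the spread between fish. A tank effect would stay in that spread or in the difference between treatments. The slide and the position on the slide came from the array headers: 3 slides held 4 arrays each, with 2 control and 2 haloperidol fish per slide. Positions 1 and 3 always held control fish and positions 2 and 4 haloperidol fish, so position and treatment cannot be told apart. The description of control replicate 2 names the haloperidol exposure and the sample number of haloperidol replicate 1, whereas its title, which gives its own sample number, and its source name say control. It was kept as control and was also left out in turn.

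Per the file headers, the authors' arrays were read with Agilent Feature Extraction, which is version 9.5 per the submitters' processing notes. The probes had been annotated on an old assembly (danRer2). The probe coordinates in the files were used here only to tell probes of a gene at separate positions from overlapping ones. The deposited scanner values used were the intensity of each spot (mean pixel brightness) and of its local background (median), before any subtraction. The deposited processed intensity of each channel had been background-subtracted with spatial detrending and dye-normalized by linear and LOWESS steps, per the file headers. The deposited log10 ratio is Cy5 over Cy3 of those processed values. The deposited flags, which are other values of 0 or 1 per spot, mark spots well above background, saturated spots and outliers. The value table of the series was set against each array and holds the same log10 ratio, rounded, in the same direction and with no further centring.

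Mean intensities were corrected with normexp (offset 50) on the median local background and normalized by loess within each array, with the 1417 control spots at weight 0, in limma 3.58.1 under R 4.3.3. Control spots and spots marked as outliers were left out (1 to 379 spots per array, with 139 to 379 on the second slide). Each array had 44407 spots, and the 2 spots of each of 21495 probes were averaged. A probe was kept if it was well above background in Cy5 on at least 6 of 12 arrays, which left 13739. Where a gene name of the array design had several kept probes, the brightest was used, which gave 11520 tested names. Of the 1773 names with more than 1 kept probe, 375 had probes whose treatment differences had opposite signs. Names were updated through a RefSeq gene table of the assembly GRCz12tu, used for names alone. By RefSeq accession 7342 probes were matched, 605 had a current symbol, 2346 had a synonym of 1 symbol, 11192 were unmatched and 10 pointed to several genes. Of the tested names, 5857 had a current symbol and 5663 kept the name of the array design.

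Haloperidol was compared with control by limma (lmFit, eBayes) over all 12 fish without covariates, two-sided, with Benjamini-Hochberg adjustment and a threshold of adjusted p 0.05. Control ovary was compared with the pool by limma's treat against a 2-fold change in the same model. Gene lists were tested with camera, also in limma, at a preset inter-gene correlation of 0.01, over the 11387 genes without a missing value and with adjustment over the 24 lists that had 5 or more measured members. Beside it stand camera with an estimated correlation, fry, and a two-sided exact permutation test of each list's mean per fish over the 924 assignments of 12 fish. Intervals are 95% confidence intervals from limma.

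The 26 lists covered steroid hormone synthesis; gonadotropin, prolactin and sex steroid receptors; dopamine and other monoamine signalling; zona pellucida proteins; oocyte and germ plasm genes; granulosa, theca and stroma genes; maturation and ovulation; vitellogenins; and yolk and lipoprotein uptake. They also covered sterol and isoprenoid synthesis, oxidative phosphorylation, ribosomal proteins, proteasome subunits, the cell cycle, chaperones and endoplasmic reticulum stress, xenobiotic metabolism and transport, antioxidant genes, and apoptosis and follicle atresia. The others were markers of vasculature, blood cells, leukocytes, liver, exocrine pancreas and gut, muscle, testis and brain. The groups, tests, lists, main settings, most of the alternatives and the rule for named genes were fixed before the data were examined. The rule named genes past the threshold, or else the 5 with the smallest p in each direction, with a symbol that is not a placeholder. It also named a fixed set of reproductive endocrine genes with cyp1a, up to 4 members of each called list, and the 5 highest and 5 lowest symbols of ovary against pool. Of all list members, 12 in 10 lists were matched by the name of the array design alone and have another current symbol. The value of 1 member of the dopamine and monoamine list is not reported here.

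The methods were tested on simulated data with the spread of these arrays, in 5 runs of 11520 genes with 200 changed genes. For haloperidol against control, 73.6% of genes changed by 1 log2 unit and 95.4% of genes changed by 2 log2 units were called, with 11.6 false calls per run. These shares hold for 200 changed genes. With fewer changed genes the adjusted threshold is harder to pass, and that case was not simulated. All 3 lists shifted by 0.5 log2 units were called, beside 0.4 unshifted lists per run. Simulated genes varied independently of each other, whereas the 3 lists called below had estimated correlations of 0.37 to 0.58 between members. The count of 0.4 therefore does not give the error rate of camera for such lists. For ovary against pool, 90.0% of genes lower by 2 log2 units and 99.4% of genes lower by 3 log2 units were called, with 0 false calls. Unchanged genes were simulated at a log2 ratio of 0, without dye bias or normalization, so the 0 false calls do not cover these.

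Alternatives changed the background correction, the normalization within and between arrays, the filter on dim probes, the choice of probe, the source of values, the prior variance, array weights, slide and sample number blocks, the channel, the set test and the fish included. Outlier spots were kept, slide and number blocks were combined, exact tests of list means were run and the Cy3 channel was tested alone as alternatives chosen after seeing the data. Median Cy5 intensity per array ran from 887 to 1417 and median Cy3 intensity from 546 to 828, and 60.4% to 68.0% of probes were well above background in Cy5. The number of arrays limits the precision. No tested gene was below background on every array of a treatment (0 genes), and 1 was saturated on every control array and 1 on every haloperidol array.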

Results

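The ovary transcriptome of 6 zebrafish in control water and 6 zebrafish exposed for 96 h to 50 µg/L haloperidol was measured against one common pool of gonad, brain and liver RNA. Replicate spots of a probe on an array differed little, with a median SD of 0.05 on the log2 scale, and the Cy3 pool signal had a median SD of 0.15 between arrays of a treatment, against 0.34 for the Cy5 ovary signal. The log2 ratios of fish pairs of one treatment correlated across genes with a median r of 0.880 over 30 pairs, and those of pairs from different treatments with 0.881 over 36 pairs, where genes are not independent replicates. Pairs on one slide had a median r of 0.890 and pairs on different slides 0.879. Between slides, 301 genes passed limma's adjusted p of 0.05 and 1855 had an unadjusted p under 0.05.

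The first comparison asked which ovarian transcripts differ after exposure to a dopamine receptor blocker. No gene rose or fell past the threshold (0 of 11520 in limma, lowest adjusted p 0.755), and 297 had an unadjusted p under 0.05, of which 99 were higher and 198 lower, where chance alone gives 576. The median gene had a 95% half-width of 0.35 on the log2 scale, and for 90.8% of genes the whole interval lay within a 2-fold change either way. The genes nearest to a call with higher values were znfl2a, a zinc finger gene, at 1.72 (95% interval 1.08 to 2.36), galcb, a galactosylceramidase gene of lysosomal lipid breakdown, at 0.84 (0.31 to 1.36), and klhl7, a ubiquitin ligase adaptor gene, at 1.60 (0.60 to 2.59). Among the genes nearest to a call with lower values were phb2b, a prohibitin gene of the inner mitochondrial membrane, at -0.57 (-0.86 to -0.29), actl6a, a subunit of chromatin remodelling complexes, at -0.49 (-0.74 to -0.25), and bnip4, a gene of the mitochondrial BNIP family, at -2.13 (-3.34 to -0.92). All 6 haloperidol fish lay above the control mean for the genes of the first group and below it for those of the second. These genes were picked by their p in the same fish, so that count is no separate support. For bnip4, haloperidol replicate 6 had -0.17 against a control mean of -0.14. Haloperidol replicates 3 (-0.61) and 6 lay within the control fish (-0.85 to 0.32), whereas the other haloperidol fish had -3.47 to -2.95.

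The other genes nearest to a call were ttc4, a co-chaperone gene, at 0.52 (0.18 to 0.85), and gli2a, a transcription factor of hedgehog signalling, at 0.28 (0.08 to 0.47). With lower values these were zic5, a zinc finger transcription factor of neural development, at -0.51 (-0.77 to -0.24), and fgf1a, a fibroblast growth factor gene, at -0.97 (-1.52 to -0.42). None of these 10 genes passed limma's threshold, with adjusted p values of 0.755 for znfl2a and 0.945 for the rest. For znfl2a, control replicate 6 had 0.42 whereas the other control fish had -1.47 to -1.03, and without that fish the difference was 2.0 with limma's adjusted p of 0.00068, the 1 gene called under any alternative (its adjusted p ran up to 0.9999 in others). The klhl7 probe was well above background on 3 control and 6 haloperidol arrays, and the gli2a probe on 3 control and 5 haloperidol arrays. A second probe of actl6a had -0.60, and a second probe of bnip4 had -1.21, with an SD of 1.47 between haloperidol fish at the main bnip4 probe.

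**Figure D1:**
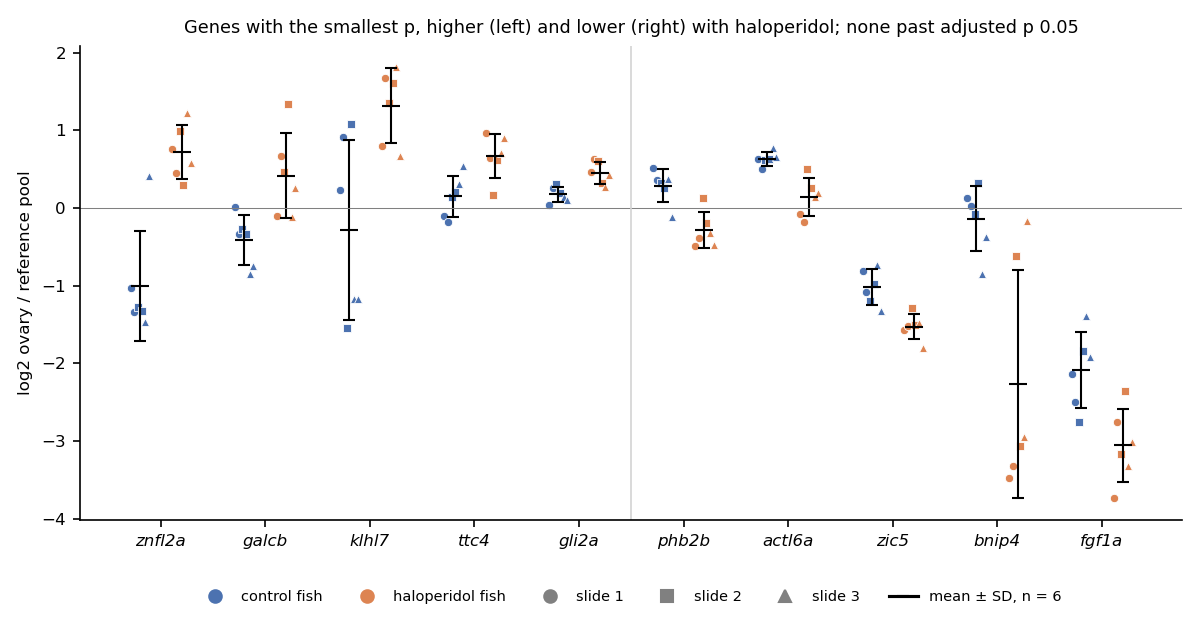
Log2 ratio of ovary over reference pool (vertical axis) for the 5 genes with the smallest p and higher values (left) and the 5 with lower values (right) after haloperidol, with a point per fish, colour for treatment, shape for slide and bars for mean and SD of 6 fish. For znfl2a the mean was -1.0 in control and 0.72 in haloperidol fish, and 0 of the 10 genes passed limma's adjusted p of 0.05.

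Genes of ovarian steroid synthesis, which feeds oestrogen and progestin production, lay on both sides of 0. The steroid list had 15 measured members, 6 higher and 9 lower, with a median of -0.10 and a mean of -0.11 (camera adjusted p 0.722). star, which carries cholesterol into mitochondria, differed by -0.15 (-0.72 to 0.42), and cyp11a1.1, the side-chain cleavage enzyme, by 0.03 (-0.20 to 0.27). cyp17a1, the enzyme on the way to androgens, differed by 0.08 (-0.47 to 0.62), hsd3b2 by 0.36 (-0.29 to 1.00) and cyp19a1a, the ovarian aromatase that makes oestradiol, by 0.42 (-0.44 to 1.28). The list's lowest value was -1.04 for hsd17b3, with a limma p of 0.0320 before adjustment. The list of gonadotropin, prolactin and sex steroid receptors had 10 measured members with a median of -0.10 and a mean of -0.13 (camera adjusted p 0.470). The receptor of follicle-stimulating hormone, fshr, differed by -0.11 (-0.42 to 0.21), and that of luteinizing hormone, lhcgr, by -0.57 (-1.26 to 0.12), where its probe was well above background on 5 control and 3 haloperidol arrays. The oestrogen receptor genes esr1 and esr2b differed by -0.31 (-0.65 to 0.03) and -0.21 (-0.77 to 0.35).

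The yolk protein receptor gene vldlr differed by 0.25 (-0.25 to 0.76), amh, a growth factor gene of granulosa cells, by -0.30 (-0.56 to -0.03) and cyp1a, a marker of aryl hydrocarbon receptor activation, by 0.01 (-0.42 to 0.43). amh had a limma p of 0.0323 before adjustment and lay below the control mean in 6 of 6 haloperidol fish. The dopamine D2 receptor genes were at or near background in ovary: drd2a, drd2b and the prolactin receptor gene prlra were well above it on 0 arrays, drd2l on 2 and esr2a on 1. The dopamine and monoamine list had 4 measured members, too few for camera, among them mao, which degrades monoamines, at -0.34, slc6a3, the dopamine transporter, at 0.20 and ddc, the decarboxylase that makes dopamine, at -0.61. The 2 measured vitellogenins, yolk precursors made mainly in liver, were vtg3 at 0.51 and vtg7 at -0.32. pgr, vtg1, gdf9, bmp15 and drd1 were not found by name on this array and were not analysed here, and the probe that the array design names hsd3b1 belongs by its accession to hsd3b2, given above.

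**Figure D2:**
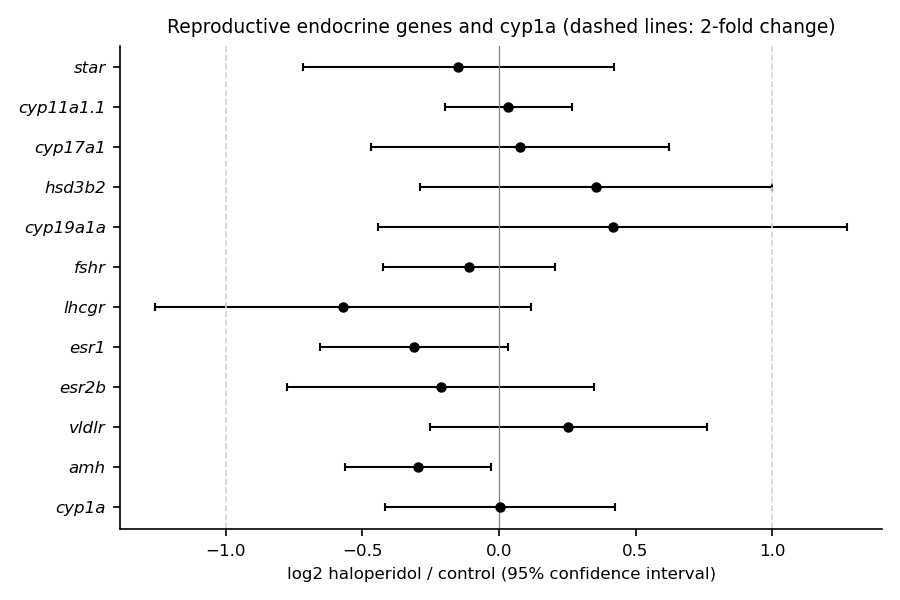
Difference between haloperidol and control fish (horizontal axis, log2) for 12 genes, which are reproductive endocrine genes and cyp1a, with a point for the estimate and a bar for limma's 95% interval over 6 fish per treatment; dashed lines mark a 2-fold change. The intervals were widest for cyp19a1a (-0.44 to 1.28) and lhcgr (-1.26 to 0.12).

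Of the 24 testable gene lists, camera called 3 at its preset correlation: exocrine pancreas and gut markers lower, leukocyte markers lower and zona pellucida genes higher. In none of the 26 lists did a member pass limma's adjusted p, with 0 members over all genes and 0 when adjusted over the list alone. None of the 3 calls held with an estimated correlation (adjusted p 0.887 for each), with fry (adjusted p 0.791 for each) or with an exact permutation test of the list mean (adjusted p 0.735 for each). With slide as a block, 0 genes passed limma's threshold, 425 had an unadjusted p under 0.05, and camera called the same 3 lists.

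The zona pellucida list, whose proteins form the egg envelope around the oocyte, had all 11 measured members higher, with a mean of 0.25 (camera adjusted p 0.00100; with an estimated correlation p = 0.0851 and adjusted p 0.887). Examples were zp2.5 at 0.41 (-0.02 to 0.84), zpcx at 0.57 (-0.19 to 1.32), zp3a.1 at 0.23 (-0.06 to 0.52) and zp3d.1 at 0.19 (-0.11 to 0.49). The exact permutation p of the list mean was 0.141, and the difference was 0.21, 0.12 and 0.41 within slides 1, 2 and 3 and 0.25 with slide as a block. The mean was 0.01 with scaling between arrays and 0.11 with Cy5 alone, where the call ended (camera adjusted p 0.668 and 0.194), and 0.17 without control replicate 4. With array weights it was 0.40.

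The pancreas and gut list, which holds digestive enzymes, islet hormones and gut genes, had 12 of 13 measured members lower, with a mean of -0.50 (camera adjusted p 0.000483; with an estimated correlation p = 0.140 and adjusted p 0.887), a direction that turned to 0.46 with scaling between arrays (camera adjusted p 0.304). Among the enzymes, the carboxypeptidases cpa4 and cpa5 had -0.82 (-1.46 to -0.19) and -0.56 (-1.22 to 0.10), and the lipase cel.1 had -0.68 (-1.33 to -0.04). Villin, vil1, of the brush border had -0.51 (-0.97 to -0.05). All 13 members, each well above background on at least 6 of 12 arrays, lay below the pool in control ovary, with a median of -2.82. The exact permutation p of the list mean was 0.188, and the difference was 0.05, -0.79 and -0.76 within slides 1, 2 and 3 and -0.50 with slide as a block. Without control replicate 4, the fish with the highest level of this list at 1.51 above the mean of all fish, the list had -0.25 (camera adjusted p 0.0285), and with array weights it had -0.80.

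The leukocyte list had 16 of 17 measured members lower, with a mean of -0.29. The 16 members without a missing value, which camera tested, had a mean of -0.31 (camera adjusted p 0.0124; with an estimated correlation p = 0.214 and adjusted p 0.887), a direction that turned to 0.09 with scaling between arrays (camera adjusted p 0.366). Means under other settings, slide as a block and fish left out included, are over all 17 members. The permutation test, the differences within slides and the levels per fish are over the 16. lyz, the lysozyme gene of neutrophils and macrophages, had -1.05 (-1.80 to -0.31) with -0.86 at its second probe, and il1b, an inflammatory cytokine gene, had -0.47 (-0.94 to -0.01). cxcr4b, a chemokine receptor gene, had -0.57 (-1.51 to 0.36) and lck, a T cell kinase gene, -0.25 (-0.69 to 0.20). The exact permutation p of the list mean was 0.294, and the difference was -0.06, 0.06 and -0.95 within slides 1, 2 and 3 and -0.30 with slide as a block. The call ended without control replicate 2 (-0.20, camera adjusted p 0.171), the fish with the conflicting description, and without haloperidol replicate 6 (-0.10, camera adjusted p 0.380), and without control replicate 3 the mean was -0.44. Relative to the mean of all fish, haloperidol replicate 6 had -1.06 for this list and was also lowest for granulosa, theca and stroma genes (-0.71), blood cell markers (-0.85) and vasculature markers (-0.39), and control replicate 3 was lowest of the control fish for the same lists (-0.64, -0.61, -0.44 and -0.28).

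**Figure D3:**
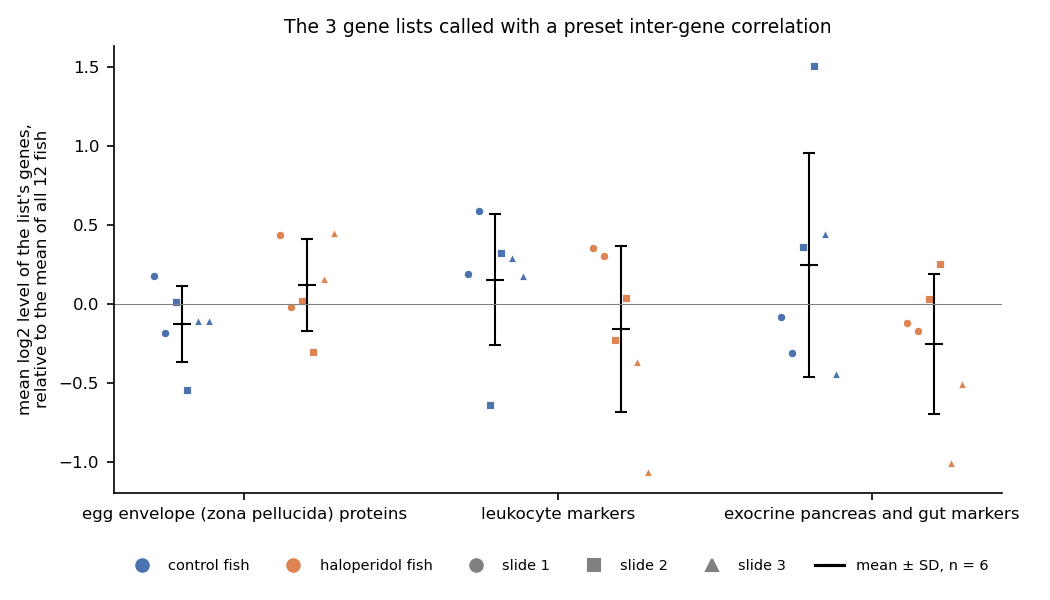
Mean log2 level of the genes of each of the 3 lists that camera called (vertical axis, relative to the mean of all 12 fish), with a point per fish, colour for treatment, shape for slide and bars for mean and SD of 6 fish. The treatments overlapped in each list, with exact permutation p values of 0.141, 0.294 and 0.188 from left to right, and with scaling between arrays the leukocyte and pancreas lists turned to 0.09 and 0.46.

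The remaining lists were not called at the main settings. Among ovarian cell groups, granulosa, theca and stroma genes had 17 of 19 members lower (median -0.13, mean -0.16, camera adjusted p 0.143), and oocyte and germ plasm genes had a median of 0.01 over 23 members (mean -0.04, camera direction up, adjusted p 0.789). That list counted the probe the array design names sycp3, which is chpt1 by its accession (-0.22), where another probe now named sycp3 had -0.25. Maturation and ovulation genes had a median of -0.08 and a mean of 0.02 over 18 members (camera direction down, adjusted p 0.767), and genes of yolk and lipoprotein uptake a median of 0.02 and a mean of 0.01 over 21 (camera adjusted p 0.316). In energy metabolism and protein turnover, oxidative phosphorylation had 42 of 49 members lower (median -0.05, mean -0.09, camera adjusted p 0.0968) and ribosomal proteins 51 of 70 lower (median -0.08, camera adjusted p 0.130). Proteasome subunits had a median of -0.05 over 44 members (camera adjusted p 0.364), chaperones and endoplasmic reticulum stress genes 0.08 over 28 (camera adjusted p 0.0891) and sterol synthesis genes -0.09 over 16 (camera adjusted p 0.566). Cell cycle genes had a median of -0.04 over 36 members and antioxidant genes -0.05 over 23 (camera adjusted p 0.789 for both). Apoptosis genes had a median of -0.06 and a mean of 0.03 over 22 members (camera direction up, adjusted p 0.566), and genes of xenobiotic metabolism a median of -0.16 over 24 (camera adjusted p 0.143).

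Markers of other cell types and tissues were not called either. Vasculature markers had a median of -0.02 and a mean of -0.03 over 8 members and muscle markers -0.01 and -0.03 over 14, with camera's direction up for both (adjusted p 0.789 for both). Blood cell markers had a median of -0.29 over 7 members (camera adjusted p 0.364), liver markers 0.09 over 17 (camera adjusted p 0.788), testis markers -0.07 over 9 (camera adjusted p 0.676) and brain markers -0.08 over 18 (camera adjusted p 0.169).

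The second comparison set control ovary against the reference pool, a mix of gonads, brains and female livers. Transcripts of liver, brain and digestive tissue were far lower in ovary. The labels name no gut or pancreas in the pool, and the source of its digestive transcripts was not tested. Of 11520 genes, 1117 were lower than in the pool by more than 2-fold and 2 were higher (limma treat, adjusted p 0.05), and 602 of the lower ones had a symbol that is not a placeholder. The count of 2 was 6 without control replicate 1, 4 without control replicate 2 or 4 and 1 without control replicate 5, and haloperidol ovary had 9. The lowest symbols were pla2g12b, a phospholipase family gene, at -7.04, agxtb, an aminotransferase of liver peroxisomes, at -6.97, chia.1, a chitinase gene, at -6.55, pah, phenylalanine hydroxylase, at -6.28 and mat1a, the liver methionine adenosyltransferase, at -6.26, with SDs from 0.30 to 1.32 between control fish. The pla2g12b probe was well above background on 4 of 6 control arrays and the pah probe on 5 of 6, so background limits how low these values go. All 17 measured liver markers passed with a median of -3.51, as did 16 of 18 brain markers (median -3.07), 10 of 13 pancreas and gut markers (median -2.82) and both vitellogenins (median -4.14). Genes of xenobiotic metabolism had a median of -1.65, with 13 of 24 lower.

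Blood cell markers had a median of -2.0 with 3 members lower, testis markers -1.53 with 4, leukocyte markers -1.08 with 1 and ribosomal proteins -0.81 with 8 (limma treat). The zona pellucida list had a median of 0.43, the oocyte and germ plasm list 0.42 and the cell cycle list 0.34, and none of their members was higher by the test. The 5 highest symbols were tbx20, a T-box transcription factor gene, at 1.61, mid1ip1l, a gene of the early embryo cytoskeleton, at 1.60, tfap2a, a transcription factor gene of neural crest, at 1.59, zp2.3, a zona pellucida gene, at 1.53 and htr5ab, a serotonin receptor gene, at 1.52. These 5 did not pass limma's treat test (adjusted p 0.232, 0.0516, 0.975, 0.0691 and 0.240). The 2 that passed have no symbol and were chosen after their values were seen: ENSDART00000042381 at 1.53 (adjusted p 0.0148) and TC287044 at 1.82 (adjusted p 0.00445). Between treatments, tfap2a differed by -2.18 (-3.68 to -0.68), with a limma p of 0.00799 before adjustment and an adjusted p of 0.945.

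The split between higher and lower genes depended on the normalization, and no dye was swapped. With the scanner's processed values 764 of 1883 genes past the test were higher (40.6%), with median centring 2110 of 2818 (74.9%), and at the main settings 0.179%.

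**Figure D4:**
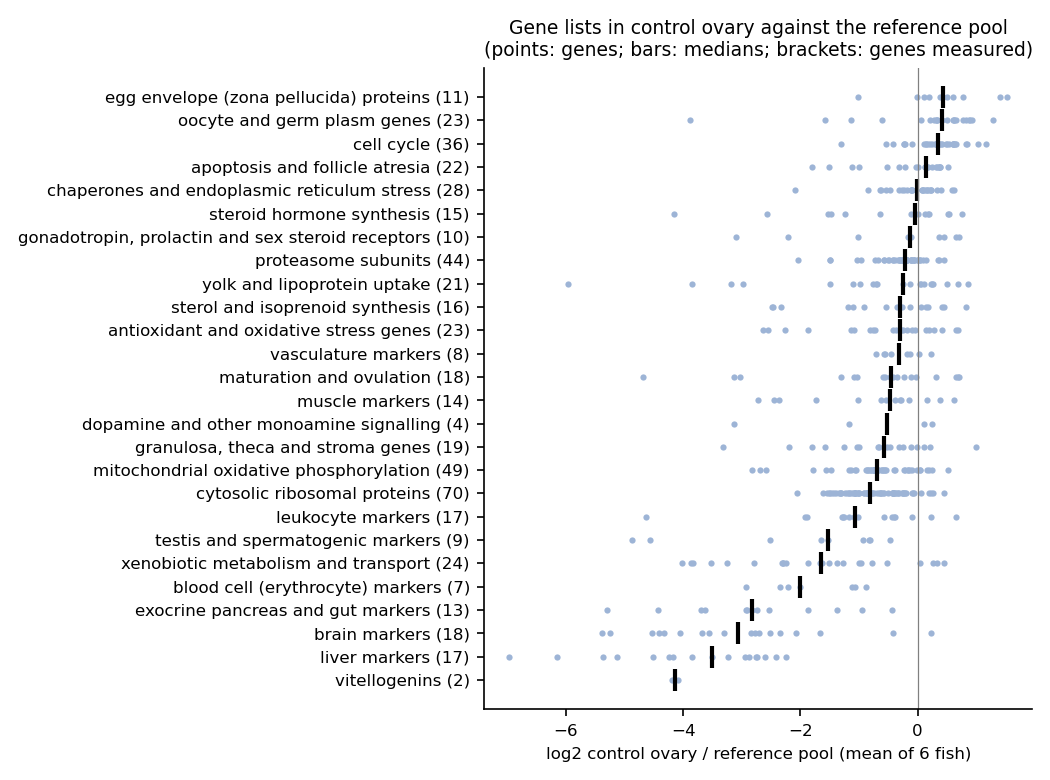
Log2 ratio of control ovary over the reference pool (horizontal axis, mean of 6 control fish) for each measured gene of the 26 lists, with a point per gene, a bar at the list median and the number of measured genes in brackets. Medians ran from -4.14 for vitellogenins and -3.51 for liver markers to 0.43 for zona pellucida genes.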

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

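Both tests of the reference channel and the test of carried-over tissue were chosen only after the result was seen. Lists in the Cy3 pool were tested by camera at its preset correlation alone. Their adjusted p values, here and below, therefore allow little for members that vary together. The other limits for explanations in this part were recorded as set before, but those for the pancreas and gut and zona pellucida lists name the direction of the call. No limit was set before for the split count of the leukocyte list or for the splits balanced over slides.

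Of 136 groups of 6 fish examined, over named genes and gene lists in each treatment, 12 had 1 fish so far from the rest that its gap to the nearest other fish, as a share of the group's range, exceeded the 95% critical value of Dixon's test, where chance alone (5% of groups) gives 6.8. For vldlr, haloperidol replicate 4 had -0.75 against 0.21 to 0.35 in the other haloperidol fish (gap 0.874 of the range), and the same fish stood apart for zpcx with -0.66 against 0.78 to 1.04 (0.847). For znfl2a, control replicate 6 had 0.42 against -1.47 to -1.03 (0.765). Among genes high or low against the pool, tbx20 had 2.57 in haloperidol replicate 5 against 0.66 to 1.33 (0.65) and mid1ip1l had 3.0 in control replicate 5 against 1.11 to 1.73 (0.67). pla2g12b had -5.27 in control replicate 1 against -7.68 to -6.81 (0.64), and mat1a had -5.09 in haloperidol replicate 2 against -7.20 to -6.44 (0.638). Among gene lists, given relative to the mean of all fish, control replicate 5 was high for oocyte and germ plasm genes with 0.50 against -0.17 to 0.03 (0.698) and low for oxidative phosphorylation with -0.08 against 0.04 to 0.09 (0.685). Control replicate 1 was high for xenobiotic metabolism with 0.69 against -0.13 to 0.10 (0.723), control replicate 2 was high for chaperones with 0.09 against -0.09 to -0.04 (0.721), and control replicate 3 was low for leukocyte markers with -0.64 against 0.18 to 0.59 (0.667).

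Chance cannot be excluded for the count of called lists. Of 100 splits of the 12 fish into groups of 6, the real one included and drawn from 462, all 100 gave at least the real 0 genes past limma's threshold, and the highest other split gave 4, but a real count of 0 fixes that outcome, so it decides nothing about genes. At an unadjusted p under 0.05, 64 splits gave at least the real 297 genes, and the other splits ran from 94 to 2624 with a median of 369. For called lists, 76 splits gave at least the real 3, with a median of 5 and a highest value of 13 in the others. The leukocyte list was called in 39 of the 100 splits. Only 29 of the splits, the real one included, had 2 fish of each group on each slide, so differences between slides enter the others. Among these 29, 12 gave at least the real count at an unadjusted p under 0.05 and 21 at least the real 3 lists, with 2624 and 11 as the highest of the others. The split with 2624, picked as the highest, was among them and had 0 genes past limma's adjusted p. Whether a structure of the samples lies behind that count was not tested.

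Exocrine pancreas and gut markers had a mean of -0.50 after haloperidol. The Cy3 pool moved by 0.09 the other way (camera adjusted p 0.000693), but the list kept -0.32 in the Cy5 channel alone, still past the threshold of camera, which argues against the reference channel as the whole source, although the call on the ratio was lost with an estimated correlation (camera adjusted p 0.887). Members that vary together from fish to fish remain a candidate explanation, since 42 of 100 splits called the list. Pancreas or gut tissue carried over with some ovaries might bring digestive and islet genes together: within treatments, the 8 digestive enzyme genes correlated with islet and gut genes at a median r of 0.419 over fish, from 0.234 for vil1 to 0.785 for sst1.1, which lies between the limits set for that test and leaves it open. An effect of haloperidol stays open as well and was not separated from these.

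Zona pellucida genes had a mean of 0.25 after haloperidol. The reference channel may account for part of it, since the Cy3 pool, the same RNA on each array, had -0.14 for these genes (camera adjusted p 0.000584), and Cy5 alone gave 0.11 (camera adjusted p 0.194). Members that vary together are a further candidate explanation, since 32 of 100 splits called the list. A larger share of oocyte RNA cannot be told apart from a change of these genes alone: oocyte and germ plasm genes shifted by -0.04, and the difference of 0.29 between the lists had a two-sided exact permutation p of 0.169. Control replicate 5 was high for the oocyte list (0.50 against -0.17 to 0.03 in the other control fish). Over all alternatives the oocyte shift ran from -0.09 to 0.06. An effect of haloperidol on egg envelope genes stays open.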

How the results depend on the processing

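Keeping outlier spots, combining slide and number blocks, the Cy3 channel alone and the exact test of list means were tests chosen only after the result was seen. The count of 0 genes changed by haloperidol held in all alternatives except without control replicate 6, and leaving out single fish gave 0 to 1. At an unadjusted p under 0.05 the count ran from 22 with the Cy3 pool alone and 154 without control replicate 5 to 979 with runs of sample numbers as a random block, and without haloperidol replicate 4 it was 839, without control replicate 3 it was 620, with array weights 742 and with no filter on dim probes 509. The runs were the lower and the higher 3 sample numbers of each treatment, and the labels do not say whether they match tanks. Their consensus correlation was -0.18, and a negative value narrows the standard error of the contrast. With slide as a block, 0 genes, the same 3 lists and 1198 genes against the pool were called. No paired analysis was possible because the labels give each fish its own sample number and the replicate numbers here only name fish.

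The 3 called lists became 5 with the scanner's processed signals, 5 with the series value table, 6 with median centring, 5 with array weights, 2 with Cy5 alone, 4 with no background subtraction, 4 with no filter on dim probes, and 2 to 7 without single fish. They became 0 with an estimated correlation, 0 with fry and 0 with the exact permutation of list means. Scaling between arrays ended all 3 calls, turned leukocyte markers to 0.087 and pancreas and gut markers to 0.46, and called 4 other lists: liver markers at 1.11 (camera adjusted p 0.000353), which stood at 0.04 before, cytosolic ribosomal proteins at 0.20, brain markers at 0.58 and the cell cycle at -0.12, each past the threshold of camera. This scaling multiplies each array's log2 ratios by a factor, so lists far from the level of the pool can move with it. Lists that moved up lay below the pool in control ovary (medians -3.51 for liver, -3.07 for brain, -2.82 for pancreas and gut). Leukocyte markers and ribosomal proteins, which also moved up, had -1.08 and -0.81. The zona pellucida and cell cycle lists moved down and lay above the pool (0.43 and 0.34). Whether these moves hold more than the scaling itself was not tested. Over all alternatives the adjusted p ran from 9.42e-06 to 0.887 for the zona pellucida list, from 0.000262 to 0.887 for leukocytes and from 7.93e-07 to 0.887 for pancreas and gut. Ribosomal proteins passed in 11 alternatives, with the opposite direction under scaling between arrays, and oxidative phosphorylation passed in 9. With an estimated correlation, the camera adjusted p was 0.887 for both. The Cy3 pool alone moved the other way from the main ratios, by 0.04 for ribosomal proteins (camera adjusted p 0.000693) and 0.03 for oxidative phosphorylation (camera adjusted p 0.0286). Of all results for lists, 780 kept direction and side of the threshold, mostly for lists not called at the main settings, 38 gained a call, 13 lost a call, 7 moved and 2 reversed.

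The 1119 genes past the test against the pool became 1883 with the scanner's processed signals, 1883 with the series value table, 2818 with median centring and 1851 (92 higher) with a test against no difference and a 2-fold limit, and 1033 to 1188 without single fish. The haloperidol coefficient gave 1269, of which 1092 were shared. The cause of these changes was not tested. Signal over background limits klhl7, gli2a, lhcgr, il1b, pla2g12b, pah and agxtb, whose probes were dim on some arrays.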

Other observations

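All tests of lists between slides and of relations between lists were chosen only after the result was seen, as were the limit to probes at separate positions and the use of these probes against spot noise; the tests of variable transcripts were otherwise set before.

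Leukocyte markers, genes of chemokine, lysozyme and antigen presentation pathways, went up and down from ovary to ovary with genes of the follicle wall, vessels and ovulation. The mean of the leukocyte list was set against that of each of the 23 other testable lists over 12 fish, after low fish had been seen to be shared, and 3 relations passed by both correlations with Benjamini-Hochberg adjustment over 23. These were granulosa, theca and stroma genes (r 0.937, permutation p 3e-05, adjusted p 0.00046; rho 0.902, permutation p 0.00016, adjusted p 0.00184), vasculature markers (r 0.912, permutation p 4e-05, adjusted p 0.00046; rho 0.923, permutation p 5e-05, adjusted p 0.00115) and maturation and ovulation genes without 1 shared member (r 0.809, permutation p 9e-04, adjusted p 0.0069; rho 0.804, permutation p 0.00246, adjusted p 0.0189). Blood cell markers passed by r alone (r 0.774, permutation p 0.00281, adjusted p 0.0162; rho 0.664, permutation p 0.0227, adjusted p 0.0872 by Benjamini-Hochberg), as did proteasome subunits (r 0.754, permutation p 0.00402; rho 0.587, permutation p 0.0496) and antioxidant genes (r 0.731, permutation p 0.00906; rho 0.685, permutation p 0.0169). For the first 3 lists, r was 0.849, 0.809 and 0.659 without the 2 fish farthest from the median, 0.913, 0.908 and 0.733 within slides, 0.906, 0.902 and 0.832 in control fish and 0.975, 0.969 and 0.918 in haloperidol fish. Within slides, r was also 0.907 for gonadotropin, prolactin and sex steroid receptors and -0.817 for zona pellucida genes, which did not pass over all fish. The low fish prompted these relations, so the p values describe them and are no independent test.

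Liver markers, the plasma protein and metabolic genes of hepatocytes, had lower ratios of ovary over pool on the third slide, where every fish had -1.01 to -0.50 relative to the mean of all fish against -0.07 to 0.67 on the other slides (slide means 0.22, 0.55 and -0.78). An exact permutation test over 34650 assignments of fish to slides gave an adjusted p of 0.00416 by Benjamini-Hochberg over 24 lists. Genes of yolk and lipoprotein uptake also differed, with slide means of 0.20, 0.01 and -0.21 (exact permutation, adjusted p 0.00416 by Benjamini-Hochberg). The other lists did not pass, and each slide held both treatments. Liver markers lay far below the pool in control ovary (median -3.51). Whether the differences between slides came from the fish or from the hybridization of each slide was not tested.

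Some transcripts differed widely between single fish of a treatment. Of all tested genes, 207 (1.80%) had an SD above 1 between fish of a treatment, with a median of 1.21, and 7 of them had an unadjusted limma p under 0.05 between treatments. Among those named here, chosen after their values were seen, dnmt1, the maintenance DNA methyltransferase, ran from -5.90 to 2.51 over fish (SD 2.61), and the zinc transporter gene slc39a13 had an SD of 2.30, tmem208 2.19, zdhhc16a 2.18 and the apolipoprotein gene apoeb 1.95. Between treatments, dnmt1 differed by 2.47 (limma p 0.0890 before adjustment), zdhhc16a by -2.0 (p 0.0993) and the transcription factor gene pax6b, with an SD of 1.64, by -2.31 (p 0.0174). The dnmt1 difference rests on control replicates 1 (-5.23) and 5 (-5.90). The other control fish (0.52 to 2.02) lay within the haloperidol fish (0.48 to 2.51). For zdhhc16a, control replicate 4 had -4.38 against -0.32 to 0.15 in the other control fish. Haloperidol replicates 3 (1.07) and 6 (-0.26) stood apart from the other haloperidol fish (-4.91 to -4.07). ctsba, a cathepsin gene, had 10 fish from -5.34 to -4.01 and 2 fish near 3, control replicate 6 with 2.89 and haloperidol replicate 3 with 2.56, and a probe under another name of the same gene ran opposite (r -0.901).

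Spot noise had an SD of 0.0531 of that between fish, but these transcripts were chosen for a large spread, so the ratio decides nothing, and noise of labelling and hybridization was not tested. Spot noise and a sequence difference under a single probe could be tested for 30 genes with another probe at a separate position: the median r between the probes within treatments was 0.959, which argues against both for the 24 above 0.7, and they stay open for the others, of which 4 were below 0.3 (ptgs2a, rab4b, sec61b and slc7a1b). Neither was tested this way for the 177 transcripts without such a probe, among them dnmt1, tmem208, zdhhc16a and slc39a13. The 8 pairs of probes at overlapping positions, looked at after their values were seen, had r of 0.938 or more, with 0.993 for slc39a13. For these pairs that argues against spot noise, but overlapping probes cannot test a sequence difference. Slide took up a median of 23.5% of the variance, just above the 22.7% that bounds 95% of random assignments, and below the 50% set for slides as the main source, so a part from slides stays open. A hypothesis that these transcripts differ in level between individual fish, or in sequence over both probe targets, stays open, and no biological explanation was tested.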
